A study of Mus musculus with 4 samples.

How the data were processed

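Total RNA of lung was isolated with TRIzol and a Promega column kit and labelled with Cy3 in a low input amplification kit, per the labels' protocols. Each of the 4 arrays took RNA pooled from 5 mice, per the labels, and the groups were sham/PBS, sham/PPE, ORX/PBS and ORX/PPE with 1 array each. The arrays were of Agilent design 074809, on 1 slide scanned on 1 day, and were extracted with Feature Extraction 10.7.1.1, per the file headers. Version 9.5.1.1 is named instead per the submitters' processing notes, and the difference could not be settled here. The processed signal of each spot is a linear intensity with background subtracted, spatial trends removed and no normalization between arrays, per the file headers. Mean and local background signals are linear intensity values too, per the file headers. Other columns of the same files are marks of 0 or 1 for background, saturation and outliers, per the file headers. The value table deposited with the series holds linear intensity values whose scale the notes do not state. All 4 of its columns had a median of 71.5, and its log2 values correlated with the processed signal at 0.9998 or more. They differed from a quantile normalization of these files by a median of 0.00364 on the log2 scale, so the scale and direction are known, and no centring of genes was seen.

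Control spots and spots marked as outliers were left out (31, 40, 54 and 46 of 59305 spots on the 4 arrays in the order above), and 0 spots were saturated. Spots of 1 probe were averaged, log2 was taken and each array's 75th percentile was subtracted. Of 56605 probes, 32994 were named by accession, 10224 by symbol and 520 by synonym through the reference table of assembly GRCm38.p6, 2574 kept the name in the file and 10293 had none. The 27195 genes named were each represented by the brightest unsaturated probe, and probe coordinates are those of the files, on build mm9. A gene counted where it was well above background on both arrays compared. Where that held on 1 array, a bound was taken from the brighter value against the higher of the dim probe's own value and the lowest signal among probes well above background, and it counted if it passed 2-fold. Bounds made 118, 89, 105 and 110 of the calls in the 4 comparisons, in the order PPE in sham, PPE in ORX, ORX under PBS and ORX under PPE. Where a gene called from 2 measured values had another measured probe, that probe went the same way for 36 of 40, 18 of 20, 58 of 62 and 41 of 47 genes, and passed 2-fold for 18, 5, 16 and 22. Probes spotted 10 times, 300 in number, had a median SD of at most 0.0363 within an array, which gives 0.0514 for a difference and covers spots, not mice. The 10 spike-in probes had median differences of -0.24, 0.09, -0.24 and 0.10 in the 4 comparisons, and 12 reference genes had medians of 0.11, 0.01, 0.05 and -0.05, from which no direction was drawn.

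The comparisons of PPE share no array with each other, nor do those of ORX. Each comparison of PPE does share an array with each comparison of ORX. With 1 array per group no test between 2 groups was possible, and the threshold was a 2-fold difference. An additive model of surgery and agent was fitted to the genes above background on at least 2 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment. It assumes that the 2 factors do not interact. Gene lists, 58 in all, were written before the data were examined, as were the comparisons, thresholds, naming rule and other settings. Each list's median was set among 10000 random lists of the same size matched on mean expression in 20 bins. Genes named are the 12 highest and 12 lowest by the smaller of 2 differences of the same sign for each factor, the 10 highest and lowest differences of PPE effects, the 5 highest and lowest of each comparison, and up to 4 members of a list per direction, or 8 for protease inhibitors. Genes known only by a clone or locus number and olfactory and vomeronasal receptors were counted and not named. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

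The steps were tested on simulated data for PPE over 20656 genes, with the noise of spots and with that of the observed contrast. Each simulation gave all genes the same noise SD and held no interaction. The limma fit called 50 of 50 genes altered 2.5-fold, 4-fold or 8-fold under both, 50 or 7 of 50 altered 1.5-fold, and 8 or 10 of 20456 unaltered ones. Real genes vary in noise and the factors may interact, so these limma counts do not show what the fit can find on the real arrays. Of 200 random lists of 25 genes in the comparison of PPE in sham mice, 5 lay outside the percentile range. After a shift of 0.3, 200 did. Other settings tried were normexp background correction with an offset of 50, quantile normalization, median centring, only probes above background on every array compared, no filter on dim probes, the mean of a gene's probes, the series' value table, a 1.5-fold threshold and a variance prior that follows intensity. Settings added after the values had been seen left out transcripts of other organs, or a part of the protease inhibitors. Probes without a gene name were left out of counts and lists, and splice forms were not analysed here.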

Results

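Lung RNA from C57BL/6J mice was measured on 4 Agilent 1-colour mouse arrays in a 2 by 2 layout, with sham surgery or ORX crossed with inhaled PBS or PPE. The labels place sampling at 3 weeks, and the RNA of 5 mice was pooled for each array. ORX was read as orchiectomy, because the series title names testosterone deficiency, and PPE as porcine pancreatic elastase, because it names elastase-induced emphysema. Each group was 1 array, so there were no replicates, every value below is a difference between pools, and the number of arrays limits the precision. The 75th percentile of the processed signal was 852.9 on sham/PBS, 829.8 on sham/PPE, 999.2 on ORX/PBS and 860.9 on ORX/PPE. Between 20132 and 20912 of 27195 genes were well above background on each array. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were above background on every array, with list medians of -0.14, 0.06, -0.05 and 0.08 in the 4 comparisons. Values are log2 differences after 75th percentile scaling unless given as folds.

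PPE was set against PBS within each surgery to show which lung transcripts went with elastase, and single genes of macrophages, elastic fibres and epithelium stood higher in both surgeries. Marco, the scavenger receptor of alveolar macrophages, was 1.80 higher in sham and 2.30 higher in ORX mice. Trem2, a lipid-sensing receptor of macrophages, was higher by 1.47 and 1.34, and Gpnmb, a glycoprotein of lipid-laden macrophages, by 1.30 and 1.51. Eln, which encodes the elastin that elastase degrades, was higher by 1.24 in sham and 2.06 in ORX mice, and another probe of it by 1.07 and 1.56. The epithelial lectin Itln1 was higher by 2.47 and 1.66, with another probe at 0.23 in ORX mice, and the anion exchanger Slc26a4 by 1.42 and 1.92. The goblet and mucous cell list that holds both had medians of -0.38 in sham and 0 in ORX mice, the latter 0.03 under normexp, and collagens had medians of 0.10 and 0.12. Inflammatory genes higher in both surgeries included the chemokine receptor Cxcr1 at 1.61 and 1.54, the acute phase gene Saa3 at 1.28 and 1.37, and the decoy receptor Il1r2 at 1.66 and 1.18. Stra6l at 1.46 and 1.80 and Slc26a10 at 1.12 and 1.23 were among the 12 highest as well. Lower in both surgeries were Speer4b at -1.16 and -1.13, the C-type lectin Cd209f at -0.85 and -1.32, the prostaglandin synthase Ptgs2 at -1.37 and -0.77, and the hyaluronan synthase Has1 at -0.72 and -0.70. Ugt8a, at -0.90 and -1.03, and Mapk10, at -0.80 and -0.97, were lower too. Background correction by normexp left Speer4b at only -0.24 and -0.16, Ugt8a at -0.13 and -0.12, Stra6l at 0.78 and 1.04, Slc26a10 at 0.78 and 0.83, Mapk10 at -0.52 and -0.60 and Cxcr1 at 0.87 and 0.82, and brought Itln1 to 1.83 and 1.15, while Marco stayed at 1.76 and 2.22. The probe of Eln lies on mm9 chromosome 5 from 135178554 to 135178613, that of Marco on chromosome 1 from 122371115 to 122371134, and that of Trem2 on chromosome 17 from 48491537 to 48491596. In all, 21 genes were at least 2-fold higher and 2 at least 2-fold lower in both surgeries, where independent lists would share 1.41 and 0.35, and 13 lay 2-fold apart in opposite directions. Across 19320 genes above background on every array, the PPE differences of the 2 surgeries correlated at 0.0187.

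**Figure D1:**
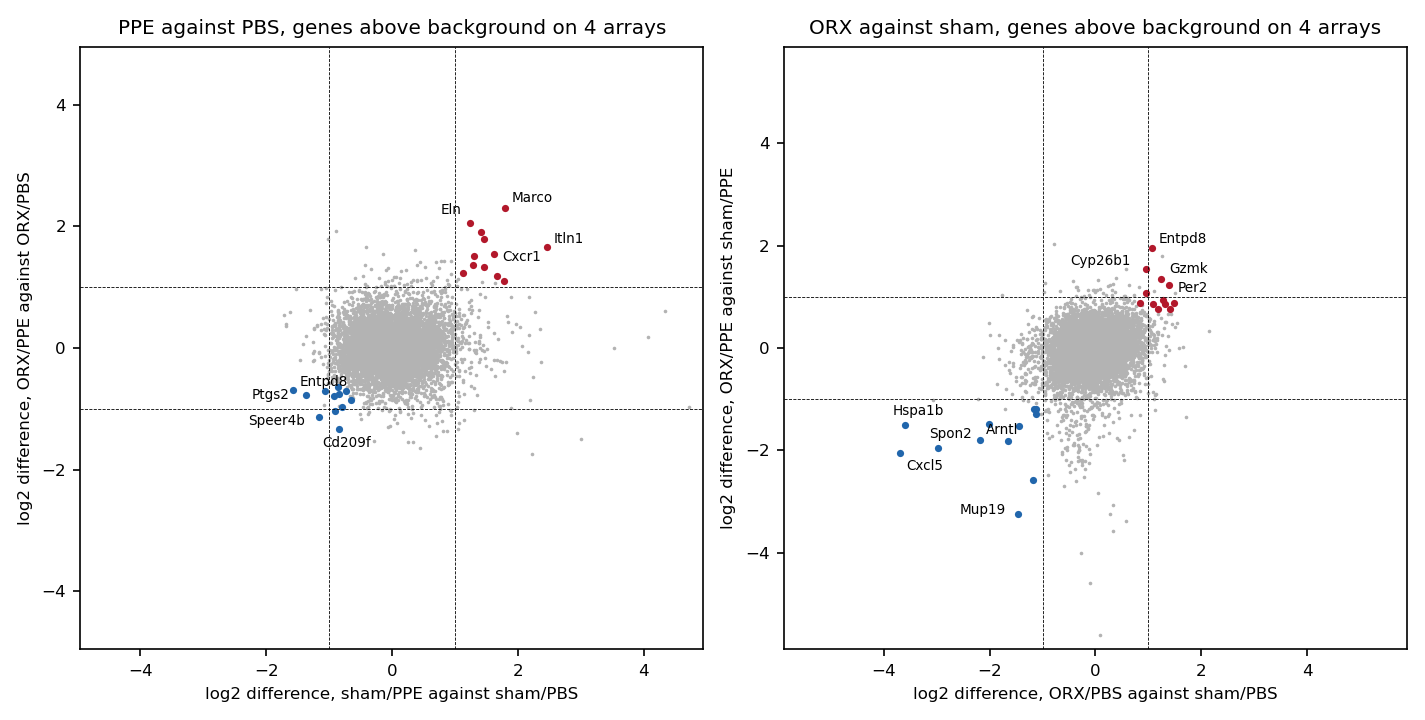
Log2 difference of each gene above background on all 4 arrays in the 2 comparisons of PPE with PBS (left, sham on the x axis and ORX on the y axis) and of ORX with sham (right, PBS on the x axis and PPE on the y axis), with the genes chosen by the naming rule in colour and dashed lines at 2-fold. Marco sits at 1.80 and 2.30 on the left, and Cxcl5 at -3.68 and -2.05 on the right.

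In sham mice, neutrophil genes stood out under PPE, with a list median of 1.16 and 13 of 24 measured members at least 2-fold higher, 0 lower and 11 neither. The calprotectin subunit S100a8 was 2.35 higher, the neutrophil collagenase Mmp8 2.28, the secreted cysteine-rich protein Retnlg 2.18 and the stefin Stfa2l1 2.07. The list of alveolar and alternatively activated macrophages had a median of 0.62, with 7 of 27 members at least 2-fold higher, 0 lower and 20 neither. Cathepsins had a median of 0.40, with Ctse at 1.22 and the elastolytic Ctsk at 0.79, and matrix metalloproteinases one of 0.18, with Mmp9 at 1.26. Ciliated cell genes were lower, with a median of -0.52 over 34 members of which 0 passed 2-fold, Foxj1 being at -0.75 and Dnaic2 at -0.75. Smooth muscle genes had a median of -0.28, with Cnn1 at -0.89 and Myh11 at -0.66. Alveolar type 2 cell genes had a median of 0.39 and mitochondrial respiration genes one of 0.21. The largest differences of this comparison were in genes of other organs: the sperm protamines Prm1 and Prm2 were 5.86 and 4.34 higher, the transition protein Tnp1 3.53, the cardiac peptide Nppb 4.71 and the imprinted RNA H19 4.07. Background correction by normexp left Prm1 at 3.84, Prm2 at 2.97, Tnp1 at 2.11, Nppb at 3.56 and H19 at 2.74. Ucp1, the uncoupling protein of brown fat, was at least 207-fold higher, with its probe on mm9 chromosome 8 from 85821788 to 85821847, and normexp brought that bound to 4.83 on the log2 scale. The heat shock genes Hspa1a at -1.69 and Hspa1b at -1.68, with Nat3 at -1.62, Entpd8 at -1.57 and Rhox3a at -1.53, were lowest, though normexp left Nat3 at -0.22, Entpd8 at -0.71 and, of the cathepsins, Ctse at 0.45. Together 262 of 20859 genes were at least 2-fold higher and 94 lower.

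In ORX mice, PPE went with higher alveolar macrophage genes and with few neutrophil genes past 2-fold. The alveolar and alternatively activated macrophage list had a median of 0.25, with 6 of 27 members at least 2-fold higher, 0 lower and 21 neither, among them Mmp12, the macrophage elastase, at 1.43. Of 24 genes of monocytes and interstitial macrophages, 12 lay above 0 and 12 below, with 1 at least 2-fold lower. The neutrophil list had a median of 0.12, with 1 member higher, 0 lower and 23 neither, Retnlg being at 0.84 and Ltf at -0.81. The goblet cell gene Clca1 was 1.92 higher, Cxcl5 1.30 and Ankrd34b 1.86. Elastic fibre genes had a median of 0.13, against 0.12 in sham mice, with Ltbp2 at 0.94 and the crosslinking enzyme Lox at 0.64. Glucocorticoid response genes had a median of 0.39, with Pdk4 at 1.16 and Mt2 at 0.94. Natural killer and cytotoxic cell genes were lower at -0.23, with Xcl1 at -0.83 and Ncr1 at -0.59, and interferon response genes at -0.19. Cardiac muscle genes had a median of -0.89, with 8 of 29 members at least 2-fold lower, 0 higher and 21 neither, Nppa being at -1.49 and Pln at -1.36. Serpina1a, which encodes an alpha-1 antitrypsin, was lowest at -1.74, followed by Mybphl at -1.65, H2al1h at -1.55 and the muscle creatine kinase Ckm at -1.54. Normexp left Ckm at -0.46, Pln at -0.49, H2al1h at -0.31, Mybphl at -0.97, Serpina1a at -0.68, Ankrd34b at 0.62 and Cxcl5 at 0.60. In this comparison 147 of 21159 genes were at least 2-fold higher and 78 lower.

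ORX was set against sham under each agent to show what went with testosterone deficiency, and single genes of several kinds were lower or higher under both. The clock list as a whole had medians of 0.61 under PBS and 0.46 under PPE, with members in both directions. Cxcl5, a neutrophil-attracting chemokine, was at -3.68 under PBS and -2.05 under PPE, with its probe on mm9 chromosome 5 from 91190490 to 91190549. The matrix protein gene Spon2 was at -2.98 and -1.96, and the inhibitor gene Serpina3i at -1.65 and -1.81, with its relative Serpina3f at -1.16 and -1.19. Arntl, the clock activator BMAL1, was at -2.19 and -1.80, and 2 further probes of it had medians of -2.33 and -0.96. The gluconeogenic gene Pck1 was 4.01-fold lower under PBS and 2.78-fold lower under PPE, the heat shock gene Hspa1b at -3.59 and -1.51, and the vasopressin receptor Avpr1a at -1.12 and -1.20. The major urinary protein genes Mup19 at -1.46 and -3.24 and Mup4 at -1.18 and -2.59, with Syt10 at -1.45 and -1.53 and Sult1b1 at -1.12 and -1.29, were lower as well. Higher under both agents were the clock repressor Per2 at 1.39 and 1.23 with another probe at 0.66 and 0.55, the lymphocyte granzyme Gzmk at 1.23 and 1.35, the retinoic acid hydroxylase Cyp26b1 at 0.95 and 1.54, and Entpd8 at 1.08 and 1.96. Pcdh20 at 0.95 and 1.07, the clock output Hlf at 1.49 and 0.89, Calcr at 1.09 and 0.87 and Nat8 at 1.31 and 0.86 followed. Background correction by normexp left Gzmk at only 0.27 and 0.17, Calcr at 0.37 and 0.25, Pcdh20 at 0.31 and 0.54, Nat8 at 0.80 and 0.44, Sult1b1 at -0.48 and -0.53, Mup4 at -0.54 and -1.13 and Serpina3i at -0.91 and -1.05. It also brought Cxcl5 to -2.12 and -1.32, Mup19 to -0.89 and -1.90, Entpd8 to 0.75 and 0.98 and Serpina3f to -0.88 and -0.89, while Arntl was at -1.91 and -1.53 and Per2 at 1.40 and 1.23. The androgen receptor and its responsive genes had a median of -0.09 under both agents, and 1 of 27 members passed 2-fold, the androgen-regulated homeobox gene Rhox5, at -1.04 and -1.30 (-0.49 and -0.52 with normexp). The probe of Arntl lies on mm9 chromosome 7 from 120456978 to 120457037. In all, 10 genes were at least 2-fold higher and 26 lower under both agents, where independent lists would share 0.39 and 3.04. Another 6 lay 2-fold apart in opposite directions. The lower genes held the relatives Mup1, Mup4, Mup17, Mup18, Mup19 and Mup21, Hspa1a with Hspa1b, and Serpina3f with Serpina3i. Relatives may vary together or share signal, which the expected numbers leave out. Mup4 and Mup19 also stood high on sham/PPE, at 2.15 and 2.45 above the mean of the other arrays. The ORX differences under the 2 agents correlated at 0.195.

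Under PBS, ORX went with higher lymphocyte and antigen presentation genes and with displaced clock genes, and the lists of B cell, T cell, MHC class II and clock genes had medians above 0 under PPE too. B cell genes had a median of 0.65, with 4 of 18 members at least 2-fold higher, 0 lower and 14 neither, Ms4a1 being at 1.54 and Cd79b at 1.02. Antigen presentation genes of MHC class II had a median of 0.57, with H2-Oa at 0.97, T cell genes 0.47, with Cd8b1 at 1.06, and natural killer and cytotoxic cell genes 0.43, with Gzma at 0.89. Under PPE the medians were 0.24 for B cell, 0.21 for MHC class II and 0.26 for T cell genes, while that of natural killer and cytotoxic cell genes, 0.04, lay inside the central 95% of random lists. The differences between the agents were not tested. Alveolar macrophage, monocyte and neutrophil lists were higher under PBS as well, at 0.35, 0.33 and 0.46. PPE in sham mice shares the sham/PBS array, with medians of 0.38 for B cell, 0.40 for MHC class II, 0.15 for T cell and 0.17 for natural killer genes. A low sham/PBS array alone would raise both comparisons, so the medians under PBS cannot be credited to ORX alone. Of 20 clock genes 6 were at least 2-fold higher, 3 lower and 11 neither, with Dbp at 2.15, Per3 at 1.42, Npas2 at -1.76 (-0.68 with normexp) and Nfil3 at -1.37. The eosinophil-associated ribonucleases Ear1 and Ear2 were 1.26 and 1.01 higher, Ctse 1.68 (0.30 with normexp) and the immunoglobulin gene Ighg3 1.70. Dbp and Ighg3, ranked highest here, were 1.62 and 2.19 higher with PPE in sham mice and at 0.33 and -1.35 for ORX under PPE. Glucocorticoid response genes included Angptl4 at -1.64, Cdkn1a at -1.43 and Pdk4 at -1.40, with a list median of -0.11. Ciliated cell genes had a median of -0.28 and proliferation genes one of 0.27. Hspa1a at -3.07 and the protease gene Adamts4 at -2.22 (-1.53 with normexp) were among the 5 lowest, and 124 of 21205 genes were at least 2-fold higher and 267 lower.

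Under PPE, ORX lungs held less of the heart, fat, germ cell and neutrophil transcripts than sham lungs. Prm1 was at -6.79 by its bound, Prm2 at -4.01, H19 at -3.58, Serpina1a at -3.39 and Tnp1 at -3.24. With normexp they were at -4.09, -2.82, -2.54, -1.95 and -2.03. These genes stood high on the sham/PPE array, which this comparison shares with PPE in sham mice. Cardiac muscle genes had a median of -1.80, with 24 of 29 members at least 2-fold lower, 0 higher and 5 neither, Nppb being at -5.61 and Nppa at -4.60 (-3.95 and -4.53 with normexp). Adipose genes had a median of -0.79, with 8 of 22 lower, Cidea being at -2.60, and Ucp1 was at least 200-fold lower, a bound that normexp brought to -4.87 on the log2 scale. The neutrophil list had a median of -0.54, with 3 of 24 lower, 0 higher and 21 neither, Ltf being at -1.60 and Cxcr2 at -1.03. The airway defence gene Bpifa1 was at -1.40 and the keratin gene Krt15 at -1.79. Of the goblet and mucous cell genes 1 was at least 2-fold higher, Clca1 at 2.04, 4 were lower and 13 neither. Doc2b was 1.54 higher (0.66 with normexp) and the clock gene Cry1 1.23 (0.60 with normexp), while Nr1d1 was at -1.18. Ciliated cell genes had a median of 0.20. In this comparison 67 of 20780 genes were at least 2-fold higher and 294 lower.

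Among protease inhibitors, which the series title names, serpins and cystatins had the largest medians of the families tested, for PPE in sham mice and for ORX under PPE. The median of all inhibitors was 0.17 for PPE in sham mice, at a percentile of 100 among 10000 random lists. It was -0.12 for ORX under PPE, at a percentile of 0.05. Both comparisons hold the sham/PPE array, on opposite sides, so a high array alone would raise the first median and lower the second. They are not 2 separate results. In the first of these comparisons 13 measured inhibitors were at least 2-fold higher, 1 lower and 93 neither, and in the second 0 were higher, 15 lower and 93 neither. PPE in ORX mice gave a median of -0.03 and ORX under PBS one of 0.02. Both lay inside the central 95% of random lists, with and without normexp background correction. Their signs differed under normexp, along with a shift of the medians of all genes. By family, cystatins at 0.32 and WAP family inhibitors at 0.21 lay above that range for ORX under PBS, and the other families inside it. For PPE in ORX mice every family lay inside it. Serpina1a and Serpina1c, which encode alpha-1 antitrypsin, the main inhibitor of neutrophil elastase, were 2.23 and 1.98 higher with PPE in sham mice and at -1.74 and -1.40 with PPE in ORX mice, and another probe of Serpina1a was 0.93 higher in sham mice. Under PPE, ORX lungs were at -3.39 and -3.06 for these genes and at -2.18 for Ahsg, a fetuin made in liver. Serpina1a, Serpina1c and Ahsg were among the transcripts of other organs seen first to stand high on sham/PPE. They lay 2.42, 2.23 and 2.04 above the mean of the other arrays there, and whether lung cells made this RNA was not tested. With normexp Serpina1a stayed past 2-fold higher with PPE in sham mice and was at -0.68 with PPE in ORX mice and -1.95 for ORX under PPE, and Serpina1c was at 1.27, -0.45 and -1.66. The probe of Serpina1a lies on mm9 chromosome 12 from 105091819 to 105091878, and the close similarity of the Serpina1 genes leaves open which of them it measured. Cystatins had medians of 0.42 for PPE in sham mice and -0.71 for ORX under PPE, led by the stefins Stfa2l1 at 2.07 and Stfa2 at 1.90 in the first. The neutrophil list, which also holds Stfa2l1, had medians of 1.16 and -0.54 in the same comparisons. Serpins as a list had medians of 0.18 and -0.25 there, with 8 of 43 members at least 2-fold lower for ORX under PPE. The other families tested lay inside the central 95% of random lists in both, with medians of 0.12 and 0.04 for WAP family inhibitors, the latter 0 under normexp, 0.03 and -0.07 for Kunitz and Kazal inhibitors, and 0.02 and -0.06 for TIMPs and the alpha-2-macroglobulin family. The inhibitor Wfdc21 was higher with PPE in both surgeries, at 1.63 and 1.07, and the secretory inhibitor Slpi was 0.62 higher in sham mice. Without the stefin A family, the Serpina1 paralogs and Ahsg, a choice made after the values had been seen, the list medians were 0.12 and -0.08, at percentiles of 99.9 and 1.84, still outside the central 95% of random lists.

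**Figure D2:**
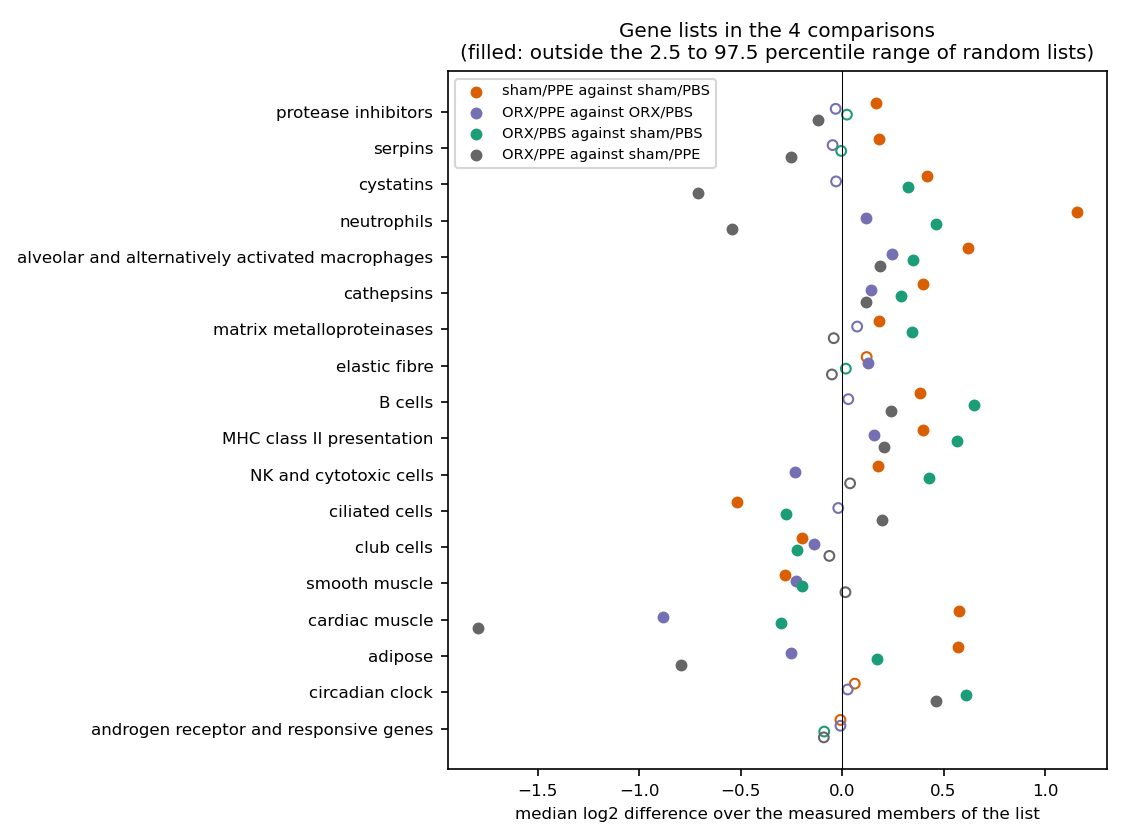
Median log2 difference (x axis) of 18 gene lists (y axis) in each of the 4 comparisons, filled where the median lay outside the central 95% of random lists. Cardiac muscle genes had the lowest median drawn, -1.80 for ORX under PPE, and neutrophil genes the highest, 1.16 for PPE in sham mice, while the medians of protease inhibitors for PPE in ORX mice and for ORX under PBS and those of serpins and cystatins for PPE in ORX mice changed sign under normexp, as did that of adipose genes for ORX under PBS, along with a shift of the medians of all genes.

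The difference between the PPE effects of the 2 surgeries asked whether ORX altered the response to elastase. It was ranked over the 19320 genes above background on every array. It was lowest for Nppb at -5.69, Nppa at -4.49, Serpina1a at -3.97, H19 at -3.90, Prm2 at -3.73 and Tnp1 at -3.53, all of which stood high on sham/PPE. Serpina1c at -3.39, Ighg3 at -3.06, Sfrp5 at -2.88 and Ahsg at -2.73 followed. Under normexp Nppa was lowest of these at -4.42, with Nppb at -3.88, Prm2 at -2.61, H19 at -2.53, Ighg3 at -2.37, Serpina1a at -2.18, Tnp1 and Ahsg at -1.97, Serpina1c at -1.71 and Sfrp5 at -1.57. It was highest for Clca1 at 2.81, Rhox3a at 2.51, Nat3 at 2.21, Tmem252 at 2.09, Hspa1b at 2.08, the checkpoint receptor Pdcd1 at 2.07 and Hspa1a at 2.05, of which normexp left Nat3 at 0.56, Tmem252 at 0.85 and Pdcd1 at 0.79. Of 19320 genes, 281 were at least 2-fold higher and 284 lower by this measure, which no replicate could test. Prm1 and Ucp1, not above background on every array, were not ranked. They were 5.86 and at least 7.69 higher with PPE in sham mice, with bounds of -0.35 and -0.21 in ORX mice. Against the mean of the other 3 arrays, 143 genes were at least 2-fold higher and 9 lower on sham/PPE, 84 and 57 on sham/PBS, 7 and 65 on ORX/PBS, and 24 and 95 on ORX/PPE.

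**Figure D3:**
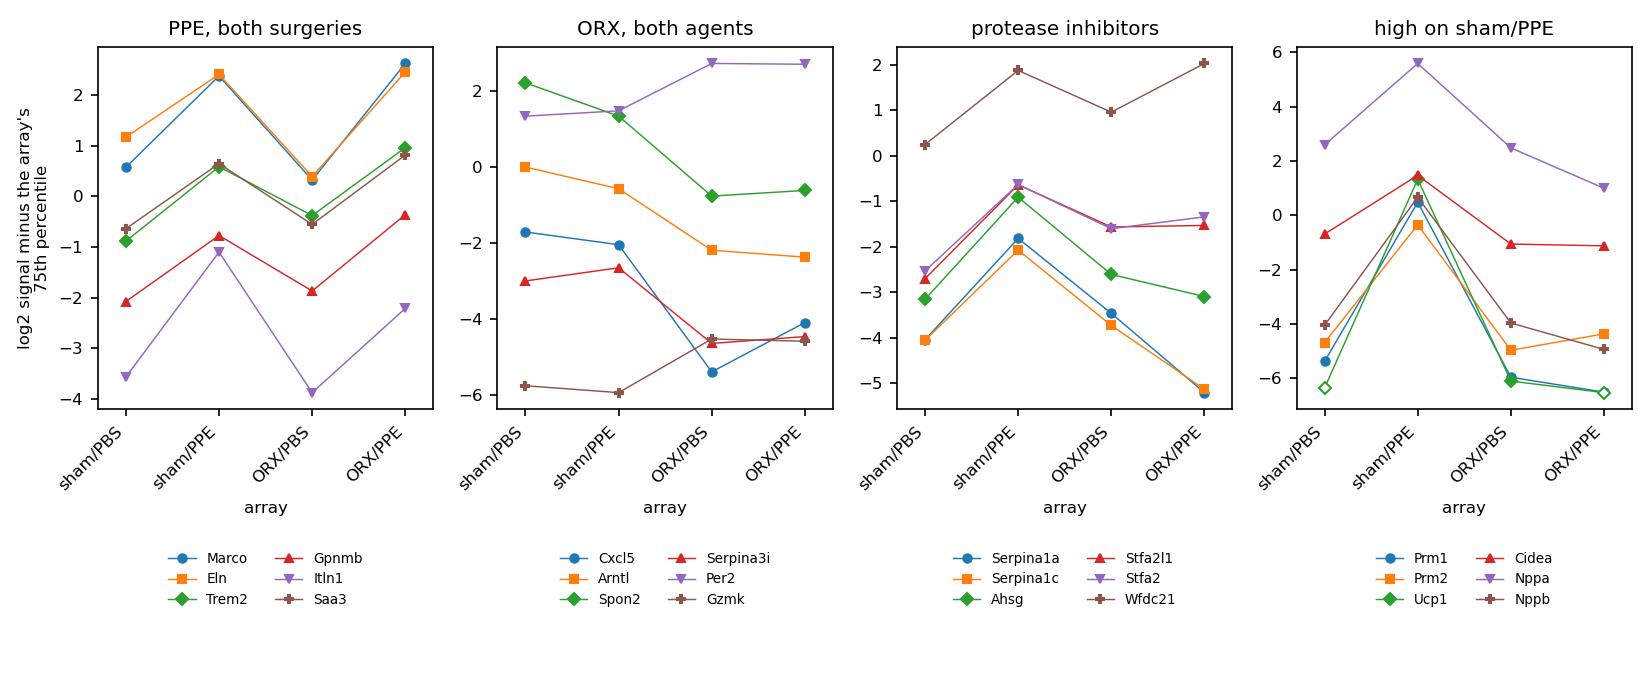
Log2 processed signal minus the array's 75th percentile (y axis) on the 4 arrays (x axis) for 6 genes in each of 4 groups, 1 point per array, open where the gene was not well above background. Marco and Eln stand higher on both PPE arrays, Cxcl5 and Arntl lower on both ORX arrays, and Prm1, Ucp1 and Nppa highest on sham/PPE.

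An additive limma fit over the 4 arrays, with 1 residual degree of freedom, called 0 genes for PPE and 0 for ORX at an adjusted p threshold of 0.05. At an unadjusted p under the same value it listed 1161 and 1638 of 20656 genes. With no differences at all, a share of about 0.05 of the genes would be listed too. With normexp background correction it called Marco for PPE, and Arntl, Per2 and Syt10 for ORX. With a variance prior that follows intensity it called 11 genes for PPE and 13 for ORX, among them Marco, Eln, Trem2, Gpnmb, Cxcl5, Arntl, Per2 and Spon2. Of 58 gene lists, 31 lay outside the central 95% of random lists for PPE in sham mice, 24 for PPE in ORX mice, 30 for ORX under PBS and 32 for ORX under PPE. Random lists leave out that genes of a list vary together, so these percentiles describe the arrays and overstate how far a list stands apart.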

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

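Chosen only after the results were seen were the separate tests of testis and of liver RNA, all tests of PPE exposure, that of the share of the clock differences kept and the rule that picked the gene lists below. Intervals in this section were taken over the genes of a list on single arrays. Genes of a list vary together and each group was 1 array, so the intervals cover neither mice nor pools. Readings that rest on them describe these arrays only.

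Effects of opposite direction between groups were looked for, and these differences were not tested, since each group was 1 array. PPE went with 2-fold differences of opposite direction in sham and ORX mice for 13 genes, among them Nppa, Alb, Serpina1a, Serpina1c and Smpx. ORX did so under PBS and PPE for 6 genes, among them Ighg3 and Cst13, at 1.24 and -1.14 and at 0.17 and -0.52 with normexp. Lists with medians of at least 0.2 in opposite directions, outside the percentile range in both comparisons, were cardiac muscle, skeletal muscle and adipose genes for PPE, whose PPE effects differed by -1.46, -0.30 and -0.90 (ORX minus sham). For ORX they were cystatins and neutrophil genes, at -1.10 and -0.82.

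Transcripts of other organs stood high on the sham/PPE array. The genes seen first included Nppa, Nppb, Prm2, Tnp1, Cidea, Mup4, Mup19, Alb, Ahsg, Serpina1a and Serpina1c. A first joint test asked that germ cell and hepatocyte transcripts, listed as not looked at before, both lie over 1 above the other arrays. The smaller median, 0.20, with the larger at 1.47, met neither of its bounds, so they were read apart. The germ cell list holds Prm1, at 5.86 the highest named gene measured on both arrays for PPE in sham mice. That list was thus not wholly apart from the values that raised the question. The germ cell list lay 1.47 above (interval 1.22 to 2.72, 19 genes), which RNA of testis in the pool may account for. Those 19 genes were kept for being above background on sham/PPE, which favours a high value there. Of them, 9 were above background on neither ORX array. All 25 listed genes, of which 19 were above background on sham/PPE and 10 on sham/PBS, had a median of 1.375. Hepatocyte genes, kept by the same rule, lay at 0.20 (0.05 to 0.46, 26 genes). They argued against liver RNA, with Ttr and Apoa1 not above background on sham/PPE. For heart and fat, PPE exposure whatever the surgery would ask for higher transcripts with PPE in ORX mice too. Cardiac muscle genes were at -0.81 (-0.91 to -0.62) and adipose genes at -0.30 (-0.44 to -0.15) there, both without the genes seen first. These transcripts were thus not higher in that pool. The amount of heart or fat may differ between pools, so PPE exposure stays open for them. Under quantile normalization the genes seen first lay at a median of 2.27 (1.66 to 2.48) above the other arrays on sham/PPE. They had been picked for standing high there, and named values past 2-fold moved by at most 0.084 between the scalings. This argued only against the choice between these scalings as the source, and other faults of normalization were not tested. PPE exposure stays open for germ cell transcripts, whose PPE difference was larger in sham mice by 0.69 (0.04 to 1.40) over the 9 measured on every array, since the values over 19 genes (0.26 in ORX mice and 1.54 for that difference) include 9 above background on neither ORX array and the genes seen first, at -0.48, had been picked partly for a low value there, while heart and brown fat carried into the pool and PPE acting in sham mice alone were not tested and stay open too.

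Clock genes lay apart between the ORX and the sham arrays. Another clock phase on both ORX arrays was tested on genes listed as not looked at before. Among them was Dbp, at 2.15 the highest named gene for ORX under PBS, so this set was not wholly apart from the values seen. The smaller gap between outputs and activators was 0.71 (-0.86 to 0.90), so another clock phase stays open. Under quantile normalization the clock genes seen first kept a median share of 1 of their differences (0.983 to 1.01, 10 values, the smallest 0.970). Their differences were known beforehand, and named values past 2-fold moved by at most 0.084 between the scalings. The share thus argued only against the choice between these scalings as the source. Arntl and Per2 lay in opposite directions, which a scaling factor common to all genes of an array does not produce. Other faults of normalization were not tested. The smaller median absolute difference under quantile normalization was 0.86 (0.67 to 1.82, 5 genes). It did not decide, since its 2 bounds overlapped between 0.75 and 1. Collection times were given for 0 groups, so time of day at collection rather than orchiectomy cannot be told apart from the surgery.

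Heat shock genes were high on the sham/PBS array. Over 18 such genes not looked at before, the median on sham/PBS was 0.38 above the other arrays (0.25 to 0.55), between the bounds set for a stress response in that tissue. A lowering by orchiectomy had a median of -0.37 in ORX/PPE against sham/PPE (-0.51 to -0.21) and one by PPE -0.14 in ORX/PPE against ORX/PBS (-0.27 to 0.06), and both stay open because their intervals cross the bounds.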

How the results depend on the processing

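Added only after the results were seen were the counts without transcripts of heart, muscle, fat, liver and testis (321, 209, 386 and 299) and the inhibitor medians of the shortened list (0.12, -0.02, 0 and -0.08). Counts below are in the order PPE in sham, PPE in ORX, ORX under PBS, ORX under PPE, difference of PPE effects, PPE in both surgeries and ORX under both agents, against main values of 356, 225, 391, 361, 565, 23 and 36. Normexp background correction gave 67, 26, 96, 93, 135, 9 and 7, no filter on dim probes 2062, 1794, 1976, 2039, 3294, 280 and 297, and a 1.5-fold threshold, by construction larger, 1910, 1233, 1991, 1466, 2264, 177 and 288. Only probes above background on every array compared gave 136 for PPE in ORX, since it leaves out the 89 calls made by a bound. Normexp adds an offset of 50 where the median processed signal was 79.2 to 95.1, which by construction makes differences of dim probes smaller. Its 67, 26, 96 and 93 calls were all among the main ones. How much of the shifts the offset made was not tested. The limma counts, 0 and 0, were 1 and 3 with normexp and 11 and 13 with the intensity prior, and 0 under quantile normalization, median centring, the value table, the mean of probes and both filters. Under normexp the share of higher genes went from 73.6% to 86.6% for PPE in sham (60.0% with no filter, 55.2% at 1.5-fold), from 18.6% to 4.3% for ORX under PPE (36.2% and 34.4%) and from 27.8% to 14.3% for ORX under both agents, and under median centring from 49.7% to 39.9% for the difference. Papln, -1.25 for PPE in sham, was 0.18 under normexp. Of 256 named values past 2-fold, 137 stayed past it under normexp, 250 under quantile normalization and with the value table, 252 under median centring and 232 with the mean of probes. No paired analysis was possible because each group has 1 array.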

Other observations

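The correlation of the PPE differences between the surgeries was 0.0187 over all genes, yet 21 genes stood at least 2-fold higher in both. With the difference between the PPE effects divided by 2, on the scale of a mean difference, 38 genes passed 2-fold, against 51 for the mean PPE difference and 121 for the mean ORX difference, and the causes were not tested.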
